A study of Drosophila melanogaster with 2 samples.

How the data were processed

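The series holds TF ChIP-seq from whole pupae of Drosophila melanogaster aged 24 hours, in a line expressing CG34367 with a C-terminal GFP tag. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp and precipitated with an anti-GFP antibody, and the 2 libraries are biological replicates 1 and 2 of 1 group. The labels do not say how many animals went into each library. P-values over peaks or genes do not measure the spread between animals, since peaks and genes are not replicates.

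4 peak lists in the narrowPeak format were used: replicate 1, replicate 2, both pooled, and the joint list thresholded on the irreproducible discovery rate. Per the deposited text descriptions, each library and the pool were called against the same control on assembly dm6, and the joint list was derived from the other lists. The peak caller and its version are not given in the sources used here. The deposited signal value is a score per peak, made by the authors' caller, with a scaling that is not given, so it was used for ranks, filters and descriptions within a list. Ratios between the libraries were centred on their median over shared peaks for that reason. The -log10 q-value deposited by the authors is capped, and all 6270 joint peaks hold the highest value, so it was not used to rank peaks. At a q-value of at most 0.05, the deposited lists hold 9154 peaks in replicate 1 and 18385 in replicate 2. The replicate and pooled lists hold 30000 peaks each, a round number that is the length of the list and not a measure of depth. Read depth is not given in the sources used here, so the precision of a single peak's signal is unknown. Intervals given for shares are exact binomial intervals over peaks or genes, cover counting error only and treat peaks as independent.

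Genes and TSS came from the Ensembl annotation, release 115, and sequence from the RefSeq assembly of Release 6, to which dm6 corresponds. All peaks lay on arms 2L, 2R, 3L, 3R, 4 and X, and 0 peaks extended past the end of an arm in that assembly. Coordinates are 1-based. Summits are the deposited summit positions. Each summit was assigned to 1 feature in the order promoter (within 500 bp of a protein-coding TSS), 5' UTR, coding exon, 3' UTR, intron and intergenic. Random positions were 1000 sets drawn on called bases of the same arms. Motif windows covered 50 bp on either side of the summit, and flanks lay 400 bp away. The test paired each summit with 1 flank chosen by a fixed seed, and the flank percentages and ratios printed for the 19 sequences average both flanks. The percentages for all sequences of 6 bases, tested with an adjustment of their own, and the GC content of flanks use the paired flank. Fisher's exact tests compared each of 21 gene lists with all other protein-coding genes, with Benjamini-Hochberg adjustment over the 21. Of the list members, 9 were matched through older symbols and 0 were left unmatched. The overlap of libraries used the 6270 strongest peaks of each, a minimum overlap of 1 bp and 1000 random placements.

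The tests, the gene lists, the sequences, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule named CG34367, the 25 genes nearest to the strongest joint peaks that overlap the strongest peaks of both libraries, the 4 members with the highest promoter signal of each list that passed (for a list below the background, its members with a peak), the 10 genes with most summits in or within 2000 bp, and the 3 peaks with the largest centred ratio in each direction. Alternatives covered the stronger 3135 joint peaks, each library alone, promoter windows of 250 and 1000 bp, motif windows of 100 bp, flanks 1000 bp away, GC-matched random positions (10 classes), peaks far from TSS, assignment to the nearest gene, and exact conditional tests with Mantel-Haenszel odds ratios, stratified by promoter window or territory length (5 strata).

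The tests of promoter share, sequences and gene lists and the overlap measure were tested on simulated data, and the other tests were not. For the promoter share, 33.6% set among 6270 simulated summits came back as 33.8%, and 4.50% of 200 unchanged sets were called. For the motif test, 10.3% set came back as 9.98%, and 4.00% of 200 unchanged sets were called. Simulated summits and flanks shared the same base composition, so the rate of false calls under the GC difference of the data is unknown. For the gene lists, an odds ratio of 4 over 13945 genes came back as a median of 4.17 in 50 sets by the stratified estimate. Of unchanged lists, 2.80% of 1000 gave a stratified exact p below the threshold, and 4.19% of 1050 an unstratified one. Each simulated gene carried a peak independently of its neighbours. In the data neighbouring genes can share a summit, so the rate of false calls for lists of clustered genes is unknown. For the overlap, 61.0% set came back as 60.9%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.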

Results

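CG34367 (FBgn0085396) encodes a homeodomain protein, a class of transcription factor that binds short AT-rich DNA sequences. Binding of the protein was mapped by ChIP-seq in whole Drosophila melanogaster pupae aged 24 hours. The animals came from a transgenic line that stably expresses the protein with a GFP tag at its C-terminus, and an anti-GFP antibody recovered the bound DNA. The series holds 1 group of 2 libraries, numbered as biological replicates 1 and 2. Each library has a deposited list of 30000 peaks, as has the pool of both. A joint list of 6270 peaks passed the threshold on the irreproducible discovery rate (IDR), which scores how well the ranks of peaks repeat between replicates. These are the 6270 strongest peaks of the pooled list. Of them, 5993 overlapped a peak in the full lists of both libraries, so membership alone does not show that a given peak repeats. Peak positions are on build dm6. With 1 group, the comparisons are between the libraries, between peaks and the rest of the genome, and between gene groups. Read depth per library is not given in the sources used here, and the control used in calling was not analysed here.

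The first comparison asked how far both libraries marked the same places. The strongest peak of the joint list lay on arm 3L from 19590428 to 19590791, with its summit 91 bp from a transcription start site (TSS) of CG14100. It ranked 1 in replicate 1 and 2 in replicate 2. Next came a peak 42 bp from a TSS of Ugalt, a UDP-galactose transporter, on the X chromosome (2703711 to 2704067). A peak at larp, which encodes an RNA-binding protein, followed on 3R (28326333 to 28326824). These ranked 2 and 5 in replicate 1, and 5 and 1 in replicate 2. Among the 6270 strongest peaks of each library, 4678 of replicate 1 overlapped a peak of replicate 2 by at least 1 bp, a share of 74.6%. Random placement of the replicate 2 peaks within their chromosome arms gave a mean of 2.88% and at most 3.62% in 1000 placements (one-sided permutation p = 0.001, the smallest they can give). Of the joint peaks, 4685 overlapped one of the 6270 strongest of both libraries, 755 of replicate 1 only, 778 of replicate 2 only and 52 of neither.

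Signal height was compared next. Across the 5993 joint peaks found in both libraries, log2 signal correlated with Spearman's rho 0.66 and Pearson's r 0.71. This is a correlation across peaks, which are not independent replicates. The log2 ratio of replicate 2 to replicate 1, centred on its median over these peaks, had an SD of 0.75, and 16.1% of peaks lay more than 2-fold from the median. The 3 peaks that stood highest in replicate 1 were nearest to CG12268 (3R, 23948882 to 23949257, centred log2 ratio -4.10), Rme-8 (2R, 9177285 to 9177706, -3.90) and MED21 (3L, 25115832 to 25116211, -3.53). The 3 that stood highest in replicate 2 were nearest to CG12643 (X, 10266119 to 10266385, 3.49), CG34269 (3L, 531243 to 531500, 3.41) and CG6163 (3L, 11365023 to 11365229, 3.37). The peaks at Rme-8, MED21 and CG6163 were in promoters, the one at CG34269 in an intron, and those at CG12268 and CG12643 between genes. The ratio moved with base composition: its median was 0.45 in the fifth of peaks with the lowest GC content and -0.35 in the fifth with the highest (rho -0.36 across peaks).

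**Figure D1:**
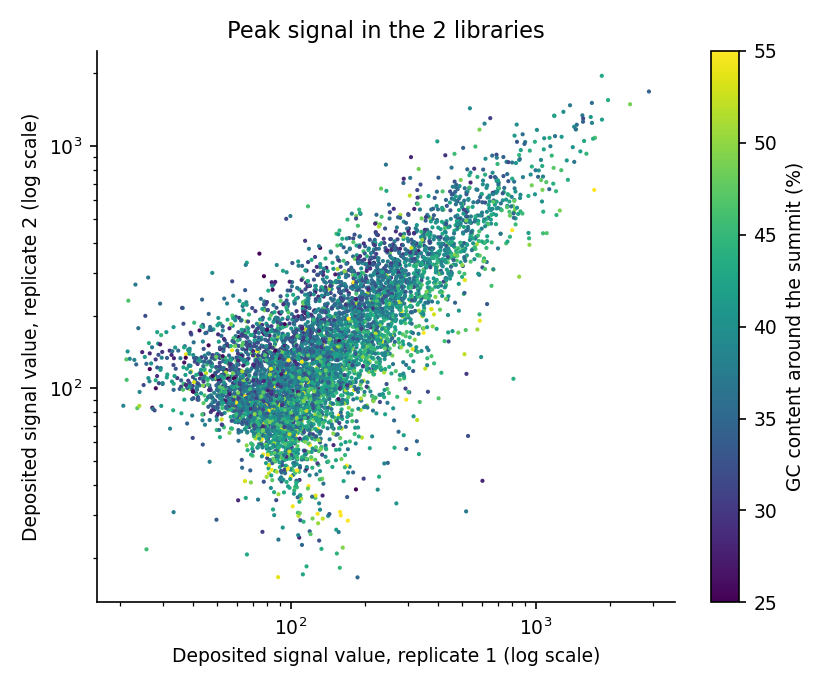
Each point is 1 of 5993 joint peaks, at its deposited signal value in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), coloured by the GC content of the 190 bp on either side of its summit. Spearman's rho is 0.66, and AT-rich peaks (dark) lie towards replicate 2.

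The second comparison asked which parts of the genome were bound. Promoters, taken as positions within 500 bp of the TSS of a protein-coding gene, held 2063 of the 6270 summits, or 32.9% (95% exact binomial interval 31.7 to 34.1%), against 11.5% of random positions. In the libraries taken singly, the promoter share was 33.2% ± 0.913 (SD, n = 2). Introns held 43.7% of summits against 39.3% at random, and intergenic sequence 21.8% against 29.9%. Coding exons were almost empty, with 9 summits (0.144%) against 13.9% at random, and with 18 and 8 in replicates 1 and 2 taken singly. The 3' UTRs held 47 (0.750% against 4.53%). Each of these shares differed from the random positions with a two-sided permutation p of 0.002, the smallest that 1000 sets can give. The share in 5' UTRs, 0.670% against 0.801%, did not (permutation p = 0.302), but it passed without replicate 1 (0.574%, permutation p = 0.044) and with a promoter window of 1000 bp (0.223% against 0.466%, permutation p = 0.006). With random positions of the same GC content, the intron share no longer differed (43.7% against 43.5%, permutation p = 0.791), and the random share in coding exons was 4.84%. With that wider promoter window the intron share did not differ either (37.2% against 36.4%, permutation p = 0.168). The median summit lay 1672 bp from the nearest TSS, and 58.3% lay over 1000 bp away.

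**Figure D2:**
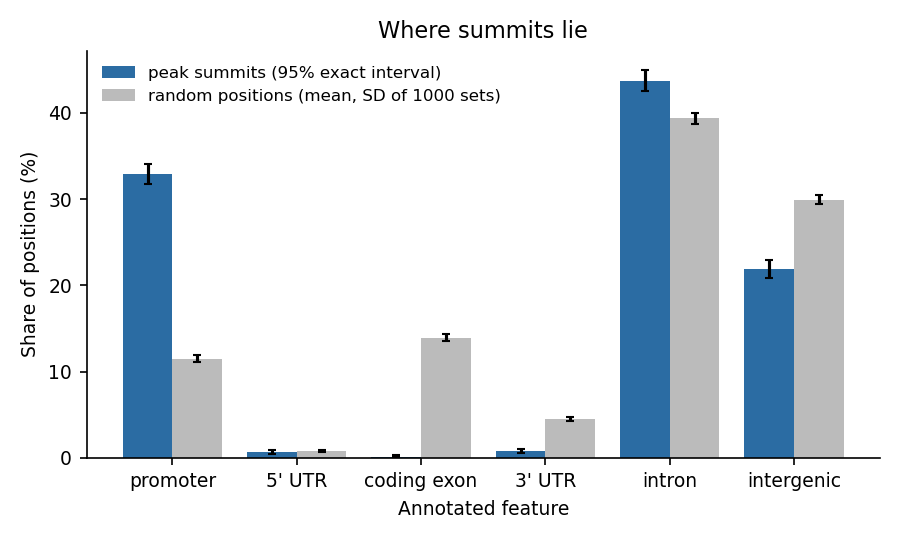
Bars give the share of 6270 peak summits (blue, with exact 95% binomial intervals) and of random positions (grey, mean and SD of 1000 sets) in each annotated feature. Promoters hold 32.9% of summits against 11.5% of random positions, and coding exons 0.144% against 13.9%.

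Over the chromosome arms, the X carried 1230 summits, 19.6% (18.6 to 20.6%), where it holds 17.6% of assembled bases (exact binomial p = 2.5e-05) and 17.0% of TSS (exact binomial p = 6.8e-08). The small chromosome 4 carried 15 summits, 0.239% against 1.00% of bases (exact binomial p = 1.3e-12). Among the 6270 strongest peaks of each library it carried 5 in replicate 1 (0.0797%) and 17 in replicate 2 (0.271%). Arm 2R lay below its share of bases, with 17.3% against 18.9% (exact binomial p = 0.0012), as did 3R with 22.6% against 24.0% (exact binomial p = 0.012), and 3L lay above it with 22.2% against 20.9% (exact binomial p = 0.012). These p-values are not adjusted over the 6 arms, the tests treat summits as independent, and the sex of the animals was not recorded. The X share was 19.1% ± 0.372 (SD, n = 2) in the 6270 strongest peaks of each library. It was above the share of bases in each (18.9% and 19.4%), and 3R was below its own in each (22.9% and 22.5%), as was chromosome 4. In the full lists of 30000, the q-value was at most 0.05 for only 9154 peaks of replicate 1 and 18385 of replicate 2. There the libraries parted. X held 16.6% of the peaks of replicate 1, below its share of bases (exact binomial p = 8.5e-06). It held 20.1% of those of replicate 2, above that share (exact binomial p = 2.1e-30). On 3R the shares were 24.98%, above that of bases (exact binomial p = 5.6e-05), and 21.4%, below it (exact binomial p = 4.9e-27). On chromosome 4 they were 0.0900%, below (exact binomial p = 6.6e-92), and 1.39%, above (exact binomial p = 8.2e-11).

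The 25 genes at the strongest peaks shared by both libraries included 13 with the summit in a promoter, 8 in an intron and 4 in intergenic sequence. Deposited signal at these peaks ran from 2362 at Reph to 4557 at CG14100, where the median of the joint list was 248. Among the 25 were the Polycomb protein gene ph-p (X, 2136938 to 2137675, signal 2631, promoter) and RYBP, which encodes a partner of Polycomb proteins (2R, 22678143 to 22678664, signal 2405, intergenic, 7633 bp from the TSS). The Brahma complex subunit gene osa had a peak in an intron (3R, 17704235 to 17704610, signal 2631), as had the forkhead factor gene jumu (3R, 10351842 to 10352274, signal 2453). The chromodomain protein gene Chro had one in its promoter (3L, 22878720 to 22879090, signal 2768). A peak nearest to cbt, which encodes a zinc finger factor, lay inside an intron of its neighbour ush (2L, 480916 to 481274, signal 2810). Lk6, a kinase gene, had an intronic peak (3R, 11760881 to 11761446, signal 3154). PNPase, which encodes a mitochondrial RNA-degrading enzyme (3R, 31404495 to 31404836, signal 2960), mRpL41, a mitochondrial ribosomal protein gene (2R, 15217588 to 15217925, signal 2845), and Art3, which encodes an arginine methyltransferase (3R, 15229360 to 15229693, signal 2791), had promoter peaks. The others were CG11050, CG4004, CenG1A, CG18549, CG31668, CG11309, CG9663, CG13323, CG9147, CG32772 and Tcs5. The RYBP peak differed most between libraries within this set, at rank 7 in replicate 1 and 136 in replicate 2.

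Some long genes held many separate peaks. The cell adhesion gene kirre had 30 summits in or within 2000 bp of its 394 kb (X, 2740384 to 3134532). Tet, which encodes a dioxygenase related to the enzymes that oxidise methylcytosine, had 24 (3L, 2786207 to 2879158), and CG1677 had 23 (X, 7281089 to 7405797). The corepressor gene sbb had 22 (2R, 18278198 to 18357296), and shn, a zinc finger gene of BMP signalling, 20 (2R, 11159086 to 11217394). CG43658 had 19, mtgo 18, and Mnt, which encodes an antagonist of Myc, 17. The cell cycle gene E2f1 and the ecdysone-induced nuclear receptor gene Eip75B had 16 each. Per 10 kb, the density was highest at Mnt (5.02 summits) and lowest at kirre (0.753). For scale, windows of 26055 bp along the genome held a mean of 1.22 summits. The genes were ranked by count without control for length. Taken singly, replicates 1 and 2 gave 31 and 29 summits at kirre and 11 and 15 at E2f1.

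The third comparison asked which DNA sequences mark the summits. The homeodomain core TAATTA lay within 50 bp of 585 summits, 9.33% (8.62 to 10.1%), against 5.37% of windows 400 bp to either side. The ratio was 1.74 (two-sided exact McNemar p = 4.6e-18). It was 8.39% in replicate 1 and 10.4% in replicate 2 taken singly, 9.37% ± 1.39 (SD, n = 2). The direction turned against random windows of the same arm and GC content, of which 11.5% held TAATTA (ratio 0.815, exact McNemar p = 7.1e-05). Summits were AT-rich, with a mean GC content of 32.9% against 44.4% in the flanks, and the fifth of peaks with the strongest signal had the lowest mean (30.5%, against 35.4% in the weakest). Of 19 sequences fixed before the data were examined, 5 were more frequent at summits than in flanks and 6 less frequent, by exact McNemar tests with Benjamini-Hochberg adjustment over the 19. Besides TAATTA, the higher ones were the paired-class dimer TAATNNNATTA (1.44% against 0.542%, ratio 2.65), the core TAATTG (ratio 1.24), the forkhead sequence TAAACA (ratio 1.63) and the GATA sequence AGATAAG (ratio 1.55, adjusted exact p = 0.030). Only TAATTA was set against GC-matched windows, and only TAATTA and the dimer against shuffled windows (described below). The other calls, higher and lower, were not controlled for the difference in base composition between summits and flanks. The GATA call was lost without replicate 1 (ratio 1.39, adjusted exact p = 0.117) and in the stronger 3135 peaks (ratio 1.46, adjusted exact p = 0.286). The lower ones were the E-boxes CAGCTG (ratio 0.498), CAGGTG (0.465) and CACGTG (0.490), the GAGA factor sequence GAGAGAG (0.624), the Zelda sequence CAGGTAG (0.481) and the CA repeat CACACACA (0.397). The 8 others, for DREF, M1BP, Grainyhead, the ecdysone receptor, AP-1, Runx, Su(H) and Scalloped, did not pass. In windows shorter than those tested, GAGAGAG lay in 1.00% at the summit and in 1.55% and 1.42% at 400 bp to either side. At 1000 bp to either side it lay in 1.05% and 1.29%. The CA repeat lay in 1.00% at the summit, 2.33% and 2.23% at 400 bp, and 1.32% and 1.44% at 1000 bp. The low ratios of GAGAGAG and the CA repeat thus reflect in part raised shares in the flanks. Neither was tested against flanks 1000 bp away. Without replicate 2, DREF (ratio 2.60) and M1BP (3.81) passed as higher and Grainyhead (0.250) as lower. Without replicate 1, Grainyhead (0.400), Runx (0.695) and Su(H) (0.60) passed as lower. With windows of 100 bp on either side of the joint summits, DREF (ratio 2.45) and M1BP (2.62) passed as higher, and Grainyhead (0.355) and Runx (0.765) as lower. In those windows the TAATTG (1.09) and GAGAGAG (0.837) calls were lost. The next 3 sets of peaks were chosen for the 19 sequences after the data were seen. At summits over 1000 bp from a TSS, AP-1 (1.43) and M1BP (9.00, from 9 summits) passed as higher. In the pooled peaks below the joint threshold, GAGAGAG turned to higher (1.16, adjusted exact p = 0.0037) and TAATTG to lower (0.936, adjusted exact p = 0.0050). DREF (2.10) and M1BP (2.72) passed there as higher, and Su(H) (0.790) and Runx (0.904) as lower. The calls of TAATTA, the dimer (1.16), AGATAAG (1.19), CAGCTG (0.957), CAGGTG (0.908), CACGTG (1.01) and the CA repeat (1.07) were lost there. At joint summits in promoters, the calls of CAGCTG (0.661), CACGTG (0.884), GAGAGAG (0.947), CAGGTAG (0.593), the CA repeat (0.724) and AGATAAG (1.11) were lost, DREF (2.20) passed as higher and the ecdysone receptor sequence AGGTCA (0.667) as lower. The 2063 promoter summits and the stronger 3135 peaks are smaller sets than the joint list. A call lost there can come from fewer peaks, and differences between sets were not tested. Of all 2080 sequences of 6 bases, 535 were higher at summits and 1098 lower, and ATATTA (21.1% against 6.25%) and AAAATA (37.5% against 17.8%) had the smallest exact p-values among the higher ones.

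**Figure D3:**
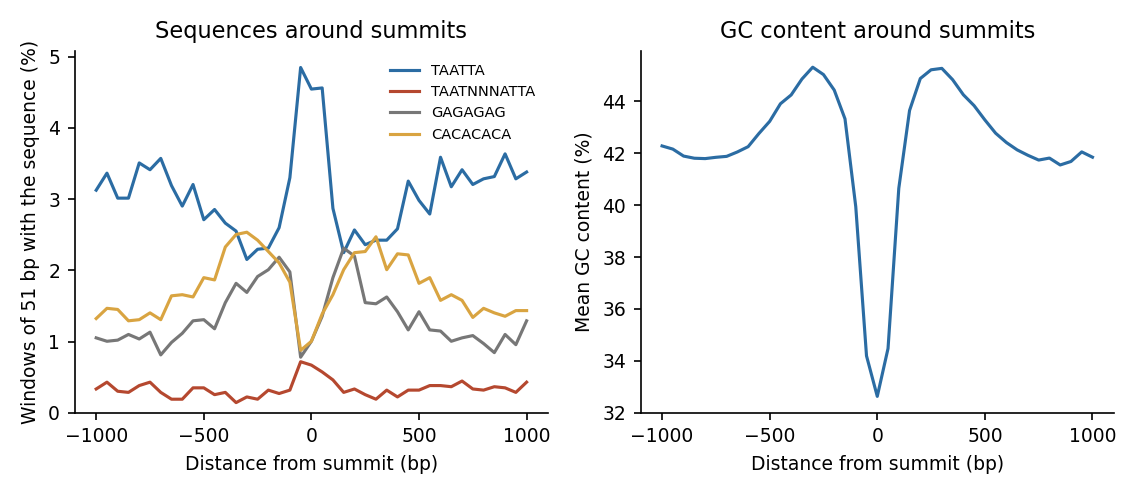
Left, share of windows holding each of 4 sequences (percent) by distance from the summit (bp). Right, mean GC content (percent) by distance from the summit. TAATTA is most frequent within 50 bp of the summit, where mean GC content, here in windows shorter than those of the text, reaches its lowest value of 32.6%.

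The fourth comparison asked which gene groups carried promoter peaks. Of 13945 protein-coding genes, 2432 (17.4%) had a summit within 500 bp of a TSS. Ribosomal protein genes stood far above this, with 69 of 93 (74.2%, odds ratio 14.0, interval 8.65 to 23.3, Fisher's exact test, adjusted p = 5.8e-32). Their summits lay at a median of 20 bp from the TSS. The 4 with the highest signal were RpS27 (3R, 25247382 to 25247653, signal 729), RpL14 (3L, 8600841 to 8601115, 701), RpL7 (2L, 10200920 to 10201168, 681) and RpS4 (3L, 13041656 to 13041932, 624), with summits 11, 15, 45 and 1 bp from a TSS. In replicate 1 alone 75.3% of these genes carried a promoter peak and in replicate 2 alone 59.1%, a mean of 67.2% ± 11.4 (SD, n = 2). Without replicate 1 the odds ratio was 7.18 (4.65 to 11.2, Fisher's exact test, adjusted p = 1.4e-18). Of 65 ribosomal protein promoter peaks found in both libraries, 62 had a centred signal ratio in favour of replicate 1, with a median log2 ratio of -1.08.

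3 groups lay below the background in Fisher's exact tests. Chemosensory receptor genes had a promoter peak in 1 of 179 (odds ratio 0.0262, adjusted exact p = 8.1e-13), at Gr77a (3L, 20739402 to 20739781, signal 138). By nearest gene their odds ratio was 0.188, and they still passed. Cuticle protein genes had 3 of 131 (odds ratio 0.110, adjusted exact p = 5.8e-07), at Cpr72Ea (3L, 16362138 to 16362517), Cpr12A (X, 13543186 to 13543565) and Cpr (2L, 6339193 to 6339572). The last is not a cuticle gene by its known function: it encodes cytochrome P450 reductase and entered the list through its symbol. The cuticle list had 1 gene with a peak without replicate 2 (odds ratio 0.0339), 2 without replicate 1 (0.0746) and 13 by nearest gene (0.464, adjusted exact p = 0.025), and passed each time. Digestive protease genes had 0 of 27 (upper bound of the odds ratio 0.692, adjusted exact p = 0.049). That call was lost under 5 alternatives, among them control for promoter window length and a promoter window of 250 bp.

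The other 17 groups did not pass after adjustment over the 21. Homeobox genes, the class of CG34367 itself, had 7 of 68 with a promoter peak (odds ratio 0.542, 0.209 to 1.19, adjusted exact p = 0.222). Without replicate 2 they had 13 (odds ratio 1.05) and by nearest gene 29 (1.16), so no direction is given for this group. In the counts that follow, the members named were chosen after their values were seen. Ecdysone response genes had 8 of 24, among them Eip93F (signal 890), Eip75B (691) and Eip74EF (404), and Wnt, Hedgehog and BMP pathway genes 13 of 44, among them sgg (1176) and nkd (455). Heat shock genes had 8 of 23, with Hsp27 at signal 2051, and fat body and hemolymph genes 7 of 20, with Lpin at 1592. Notch pathway genes had 9 of 30, led by E(spl)mdelta-HLH (979) and numb (752), and axon guidance genes 13 of 47, led by tutl (599) and unc-5 (526). Glial genes had 6 of 18 and circadian clock genes 4 of 15. Hemocyte genes had 3 of 18, proneural genes 4 of 26, muscle genes 4 of 30, and genes of the mitochondrial respiratory chain 10 of 82. Leg and appendage genes had 3 of 27, dpr and DIP cell surface genes 3 of 32, genes of neuronal excitability 3 of 40, and antimicrobial peptide genes 0 of 20. With peaks assigned to the nearest gene at any distance and territory length controlled, 4 further groups stood above the background. These were the Wnt, Hedgehog and BMP (30 of 44), ecdysone (17 of 24), axon guidance (31 of 47) and Notch (16 of 30) groups, and dpr and DIP genes (3 of 32) lay below it. Without replicate 2, axon guidance genes (16 of 47, odds ratio 2.31) and glial genes (8 of 18, odds ratio 3.57) also passed. With a promoter window of 1000 bp, the ecdysone (12 of 24) and Wnt, Hedgehog and BMP (17 of 44) groups passed above the background, and antimicrobial peptide genes (0 of 20) below it.

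**Figure D4:**
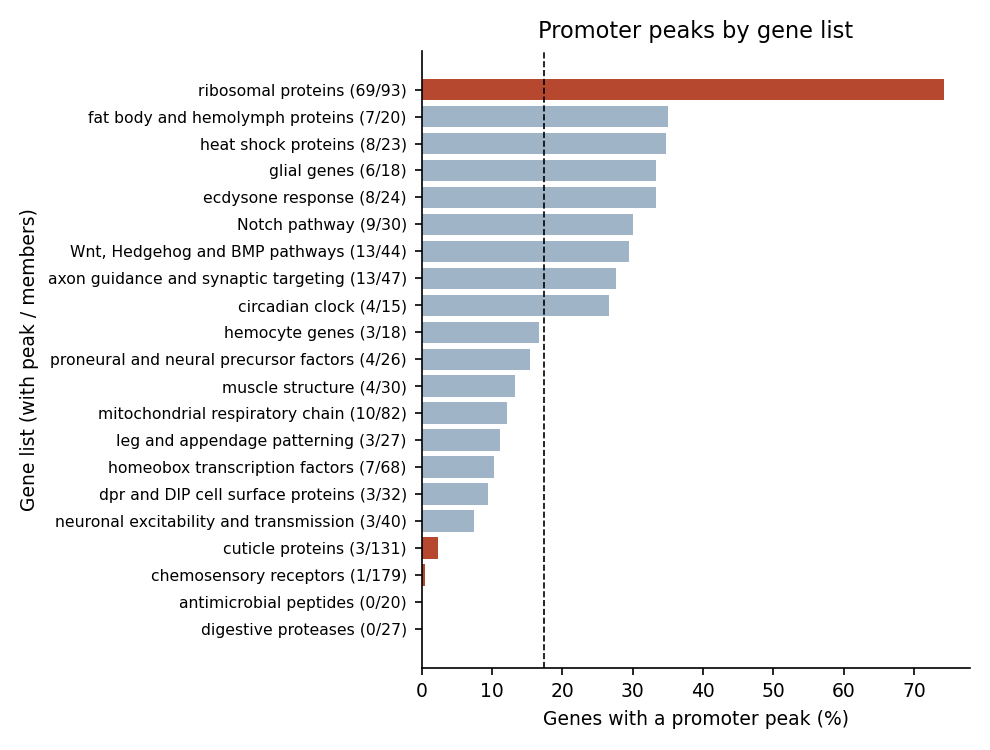
Bars give the percentage of each list's genes with a joint peak summit within 500 bp of a TSS (counts in the labels), and the dashed line the 17.4% of all protein-coding genes. Ribosomal proteins (74.2%) lie above the line and chemosensory receptors and cuticle proteins below it (red). Digestive proteases, which also passed, have no bar since 0 of 27 carry a peak.

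At the CG34367 gene itself (2L, 10347851 to 10353905, reverse strand) no joint peak lay inside the gene. Within 10000 bp of it there was 1, from 10356496 to 10356875, with its summit 2781 bp from the nearest CG34367 TSS. That summit lay in the promoter of the neighbouring gene CtsL4 and had signal 246, rank 3151. Windows of that length held as many or more summits in 49.8% of placements along the genome. Among the 6270 strongest peaks of each library, replicate 1 had 1 there and replicate 2 had 2. In the full lists, replicate 1 had 1 and replicate 2 had 5.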

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

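The tests of DREF and M1BP in the pooled peaks below the joint threshold, at joint summits in promoters and over 1000 bp from a TSS were chosen only after the data were seen.

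Chromosome 4 stood out in peaks that most comparisons of the report leave out, those beyond the strongest of each library. The full list of replicate 2 held 417 peaks on chromosome 4 and that of replicate 1 held 27, a ratio of 15.4 (exact 95% interval 10.5 to 23.7), though only 167 and 8 of these had a q-value of at most 0.05. A candidate explanation is GC-dependent recovery of DNA, since chromosome 4 is AT-rich (35.2% GC) and replicate 2 favoured AT-rich peaks. From each library's peaks per base in 22 GC classes on the other arms, 243 were predicted in replicate 1 and 373 in replicate 2. The predicted ratio of only 1.53 lay below the interval of the observed ratio, so GC content as scored here is not the whole cause. The departure lay mostly in replicate 1, with 27 peaks against 243 predicted, and less in replicate 2, with 417 against 373. What sets the rest was not tested, and no biological explanation was tested, since both libraries belong to 1 group.

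2 sequences that did not pass in the joint list passed as higher in the 23730 pooled peaks below its threshold. Of all 30000 pooled peaks, 13029 had a q-value of at most 0.05, the 6270 joint peaks among them. Most of the 23730 therefore did not reach that q-value. The DREF site TATCGATA was 2.10 times as frequent at those summits as in their flanks (0.603% against 0.287%, exact McNemar test, adjusted p = 7.2e-05). The M1BP site GGTCACACT was 2.72 times as frequent (0.303% against 0.112%, exact McNemar test, adjusted p = 0.00069). In the joint list the ratios were 1.80 and 2.08 and did not pass (adjusted exact p = 0.092 and 0.087), and the difference between the lists was not tested. The shares there were 0.590% against 0.327% in flanks for DREF, and 0.431% against 0.207% for M1BP. With only 6270 joint peaks the test has less power, so these sequences are not shown to be particular to the weaker peaks. Both passed in the joint list with windows of 100 bp on either side of the summit, at ratios of 2.45 and 2.62, and in the 6270 strongest peaks of replicate 1 alone, at 2.60 and 3.81. Neither passed in those of replicate 2 alone, at 1.37 and 1.00, or in the stronger 3135 joint peaks, at 1.62 and 1.60. At joint summits in promoters DREF passed (ratio 2.20, adjusted exact p = 0.025) and M1BP did not (1.55, adjusted exact p = 0.152), and over 1000 bp from a TSS DREF did not (0.727, from 4 summits) and M1BP did (9.00, from 9 summits).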

How the results depend on the processing

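The tests on peaks below the joint threshold and on rotated peaks, and those of the 19 sequences in promoters and far from TSS, were added after the data were seen. The promoter share (2.06 to 3.92 times random), the X share (18.9 to 19.4%) and the excess at ribosomal protein genes (odds ratio 7.18 to 19.2) kept their direction and their side of the threshold under each alternative listed for them. But in all 30000 peaks of replicate 1, of which 9154 had a q-value of at most 0.05, the X share was 16.6%, below that of bases. The number of higher sequences ranged from 4 to 7, and the rule named 17 to 25 of the 25 strongest genes. TAATTA kept both under 6 alternatives and turned in 2: the ratio was 0.815 against GC-matched windows and 0.957 below the joint threshold (exact McNemar p = 0.178), with no test of the cause beyond base composition. The overlap of libraries was 61.0% with 50% reciprocal overlap, 69.9% with summits within 100 bp, 75.7% for the 3135 strongest peaks and 56.2% for all peaks. The Spearman correlation of signal between the libraries was 0.681 with summits within 100 bp and 0.716 for all overlapping peaks. The number of lists passing went from 4 to 7 with a promoter window of 1000 bp and to 8 by nearest gene. At 1000 bp, odds ratios passed at 3.77 for ecdysone, 2.37 for Wnt, Hedgehog and BMP, and 0 for antimicrobial peptide genes. By nearest gene they passed at 4.96 for ecdysone, 3.06 for axon guidance, 3.66 for Notch, 6.17 for Wnt, Hedgehog and BMP, and 0.158 for dpr and DIP genes. In single libraries the odds ratio was 1.32 to 2.31 for axon guidance and 2.43 to 3.57 for glial genes, each of which passed in replicate 1 alone and not in replicate 2 alone. Digestive proteases lost their call with an odds ratio of 0 in the stronger 3135 peaks, at 250 bp, by strata of window length and by rotation, and of 0.182 by nearest gene. The cause was not tested in these cases. The CG34367 locus held 0 peaks among the stronger 3135, and 1 to 2 in single libraries. The pooled peaks of matching number are the joint list itself, and all peaks lie on the 6 arms, so those 2 alternatives give no other value. No paired analysis was possible because there is 1 group. Unknown depth limits any statement on weak peaks.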

Other observations

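The tests of the 12 further gene lists, of genes outside the protein-coding ones, of the signal ratio at ribosomal protein promoters and of respiratory chain genes were chosen only after the data were seen. The strata of window length had been chosen before, and were set against the ribosomal protein excess as an explanation only after their result was seen.

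In 12 further gene lists, tested together, cytochrome P450 genes had promoter peaks in 5 of 85 (odds ratio 0.294, Fisher's exact test, adjusted p = 0.030), at Cyp6u1, Cyp310a1, Cyp6a16 and Cyp6a2 among others. Rotation of the peaks along the gene order, which keeps neighbouring genes together, gave an adjusted permutation p of 0.086, so that call depends on treating neighbours as independent. Polycomb and trithorax group genes had 10 of 29, among them ph-p, brm, ph-d and E(z) (34.5%), and did not pass (adjusted exact p = 0.147). Nor did mitochondrial ribosomal proteins (18 of 73), translation factors (14 of 52), nuclear pore proteins (5 of 21), spliceosomal proteins (6 of 30), vacuolar ATPase subunits (5 of 33), proteasome subunits (4 of 48), serpins (3 of 28), odorant-binding proteins (4 of 51), the Osiris family (1 of 25) or ecdysteroid biosynthesis genes (0 of 10). Outside protein-coding genes, 10 of 290 tRNA genes had a joint summit within 250 bp (3.45%, against 2.61% for random placements, permutation p = 0.454). Neither did snoRNA genes (7 of 269), snRNA genes (1 of 32) or pseudogenes (9 of 268) differ from random placements by these permutation tests. Non-coding RNA genes had one at 403 of 3261 (12.4% against 6.32%, permutation p = 0.002, the smallest 1000 placements can give). The placements were not controlled for closeness to protein-coding TSS, near which summits were more frequent than at random.

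Ribosomal protein promoter peaks differed between the libraries more than other promoter peaks. Their centred log2 ratio of replicate 2 to replicate 1 averaged -1.15 (SD 0.66 over 65 peaks), against -0.03 (SD 0.77) over 1602 other promoter peaks and -0.13 over those weighted to the same 5 GC classes. Within these classes the two-sided permutation p was 2e-05, the smallest that 100000 permutations can give. These peaks were also narrow, with a median width of 224 bp against 380 bp over all promoter peaks and over the joint list. Width was not compared at equal signal, and their median signal was 320 against 273 at all genes with a promoter peak. Peaks are not replicates, so these values describe these 2 libraries.

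The excess of TAATTA at summits may reflect base composition. When the bases of each summit window were shuffled with dinucleotide counts kept, TAATTA appeared in a mean of 12.2% of windows, from 11.2% to 13.6% in 100 shuffles, where 9.33% was observed. The observed share lay below all 100 shuffles and below the 11.5% of GC-matched windows. TAATTA was thus rarer at summits than their base composition predicts, though more frequent than in flanks. Recognition of TAATTA itself by the tagged protein was set against base composition: among the 36 sequences of 6 bases made of A and T only, TAATTA ranked 35 by its ratio of summits to flanks. Its ratio of 1.74 (bootstrap interval over peaks 1.56 to 1.92) lay below their median of 2.18, which argues against recognition of TAATTA as the source of the excess over the joint list as a whole. The dimer TAATNNNATTA, at 1.44% of summits, lay within its shuffled range of 1.13 to 2.17%, and recognition of either sequence at a smaller set of peaks stays open.

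The excess of ribosomal protein genes outlasted strata of GC content and promoter window length, and transcription was not measured here. Transcription in most cells would, if it were the whole cause, raise the respiratory chain genes too. Their odds ratio was 0.656 (0.301 to 1.28), or 0.947 (0.427 to 1.89) without members whose symbol ends in L. Both lay below 8.65, the lower bound for ribosomal protein genes. These values argue against broad transcription alone. The comparison cannot exclude transcription at a higher level than that of respiratory chain genes, so high transcription stays open. With genes in 10 strata of the lowest GC content near their TSS, the odds ratio of ribosomal protein genes was 14.5, and with 5 strata of promoter window length 16.1, so AT-rich promoters and the number of TSS are not the whole cause. The control library and a line without the tagged protein were not analysed here, so recovery of these promoters by the antibody or the procedure itself stays open, and no biological explanation was tested.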
